A study of Mus musculus with 30 samples.

How the data were processed

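RNA from the soleus of 30 mice was sequenced on an Illumina NovaSeq from total RNA with a directional library kit, per the labels. The values deposited by the authors are raw read counts per Ensembl gene, 1 column per mouse, with no normalisation; whole numbers with a different total in each column fit that unit. The authors name cutadapt 1.16, STAR 2.7.9a, featureCounts 1.6.3 and DESeq2 1.34.0, and the mouse builds GRCm39 and mm39. The annotation release, the strand setting of the counting and any filter are not given in the sources used here. The protocol texts attached to the samples speak of people given metformin around bed rest and of myotubes, which does not match mouse soleus, so nothing was taken from them beyond the library kit. Genotype, loading, sex, strain, age and tissue come from the sample characteristics.

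The table held 56980 genes, of which 52073 had a symbol in the tables used here and 4907 were kept under their identifier. All 30 columns were matched to a labelled mouse. Symbols came from a table keyed on the Ensembl identifier, and gene neighbours from a RefSeq table on GRCm38.p6. Positions are not given, since the authors used a later build. Total counts ran from 12.1 to 20.9 M per library, so counting error is small for genes above a few CPM and the spread between mice sets the precision. The sex shown by Xist and Ddx3y matched the label in all 30 mice. No pair of libraries within a group was as alike as a duplicate would be. The letters a, b and c that end the sample titles are not explained. All groups hold all 3 letters (ambulatory controls 3, 2 and 3 mice, ambulatory mKO 2, 3 and 2, unloaded controls 2, 2 and 3, unloaded mKO 2, 3 and 3). They were used for values within letters and as an alternative covariate.

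Counts were normalised by TMM in edgeR 4.0.16 under R 4.3.3. Genes with too few counts were removed by filterByExpr with its default settings, which left 16932. A quasi-likelihood model with a term for each of the 4 groups and a term for sex was fitted to all 30 libraries with robust dispersion. The 5 comparisons were mKO against control in ambulatory and in unloaded mice, unloaded against ambulatory in controls and in mKO mice, and the interaction of genotype and unloading. A gene was called, and said to rise or fall, at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. Values after ± beside a log2 change are standard errors and beside a CPM mean standard deviations. CPM are TMM-normalised. Folds come from the model, which includes sex, and need not equal the ratio of the printed means.

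Before the data were examined, 36 gene lists were fixed, 26 of pathways and 10 of cell-type markers, together with the comparisons, the alternatives and the rule for named genes. Lists with at least 5 tested genes, 35 of them, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with the Benjamini-Hochberg adjustment over the lists of a comparison. The list of lymphocyte and neutrophil markers had 3 tested genes, none called in any comparison, and was not tested as a list. Camera with the correlation estimated for each list was an alternative. Counts adjusted over the list alone apply the adjustment to the genes of that list. The rule named, for each comparison, both catalytic AMPK subunits, the 8 called genes with the largest rise and the 8 with the largest fall among those with an official symbol and a mean of at least 1 CPM, up to 4 members of each list with the smallest p, members needed to say what did not pass, all called genes where 16 or fewer were called, and for the interaction the 10 genes with the smallest p.

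Alternatives planned in advance were median-of-ratios size factors, DESeq2 1.42.0, limma with library weights, no low-count filter, a minimum mean of 1 CPM, sex left out, the title letter as a covariate, a model of the compared groups only, and the estimated inter-gene correlation. Leaving out ambulatory mKO replicate 2, leaving it out with the title letter as covariate or with the estimated correlation, leaving out the 3 libraries highest in adipocyte transcripts (also with the estimated correlation), and leaving out ambulatory mKO replicate 4 (highest in Col1a1) or ambulatory control replicate 1 (highest ambulatory control in Myh4) were chosen after seeing the data. The procedure was tested on simulated counts with known 2-fold and 4-fold changes. The number of genes called was also set against other splits of the same mice into groups of the same sizes, 40 splits per comparison with the real one included, drawn with a fixed seed, and for 4 comparisons, after the data were seen, against 40 splits that kept the title letters of each group with the letter in the model. Relations across libraries were tested by two-sided permutation. A few genes that the rule names are not reported here.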

Results

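The data are RNA sequencing counts from the soleus, a postural muscle of the lower hindlimb, of 30 mice aged 3 to 4 months on a C57BL/6J background. Mice either walked freely for 4 weeks (ambulatory) or spent 4 weeks with the hindlimbs lifted off the ground (hindlimb unloading), and they either lacked both catalytic subunits of AMP-activated protein kinase in skeletal muscle (mKO) or were controls with floxed genes and no Cre. The groups held 8 ambulatory controls, 7 ambulatory mKO mice, 7 unloaded controls and 8 unloaded mKO mice, each with both sexes. Total counts per library ran from 15.3 to 20.9 M in ambulatory controls, 13.0 to 18.5 M in ambulatory mKO, 13.9 to 18.1 M in unloaded controls and 12.1 to 17.5 M in unloaded mKO mice. The design asks what loss of muscle AMPK does to soleus transcripts, what unloading does to them, and whether unloading acts differently when AMPK is missing. The library of ambulatory mKO replicate 2 stood apart from all others. It held 116 normalised CPM, counts scaled to library size, of the slow myosin Myh7, against a mean of 11721 ± 3569 (SD, n = 6) in the other mice of its group, and 903 CPM of the adipocyte hormone Adipoq, against 35.5 ± 54.3 CPM.

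In ambulatory mice 3 genes differed between mKO and control soleus. Controls carried no Cre, so loss of AMPK and presence of Cre are not separated in any comparison of genotypes. Transcripts of Prkaa2 (ENSMUSG00000028518), which encodes the catalytic subunit α2, fell from 213 ± 28.3 CPM (SD, n = 8) in controls to 60.3 ± 26.3 CPM (SD, n = 7) in mKO mice, a 3.71-fold difference (log2 -1.89 ± 0.26 SE, adjusted p = 0.000367). Transcripts counted for Esr1 (ENSMUSG00000019768), the gene of oestrogen receptor α, rose 14.1-fold, from 28.1 ± 4.97 to 387 ± 172 CPM (log2 3.81 ± 0.34 SE, adjusted p = 5.71e-08). Abat (ENSMUSG00000057880), a mitochondrial enzyme that breaks down the transmitter GABA, rose 1.72-fold, from 12.5 ± 2.02 to 19.6 ± 2.44 CPM (log2 0.78 ± 0.14 SE, adjusted p = 0.0255). For these genes the mKO and control ranges did not overlap in ambulatory mice, and the direction was shared by all 3 letters that end the sample titles. Prkaa1 (ENSMUSG00000050697), which encodes the other catalytic subunit, α1, did not pass. It measured 20.99 ± 2.74 CPM in controls and 17.2 ± 9.03 CPM in mKO mice (log2 -0.20 ± 0.18 SE, adjusted p = 0.891). Its log2 value was -0.51 ± 0.16 without ambulatory mKO replicate 2. Counts are per gene and not per exon, so reads from exons outside the deleted segment, and from cells other than muscle fibres, enter the values of Prkaa1 and Prkaa2.

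These 3 genes, 2 higher and 1 lower, were all that edgeR called between ambulatory mKO and control mice among 16932 tested. At an unadjusted p below 0.05 there were 1291 genes, where chance alone gives about 847, and 365 without ambulatory mKO replicate 2. A count that moves so with 1 library does not show how many genes differ. DESeq2 called 9. When the model held the compared groups alone, neither Prkaa2 (adjusted p = 0.0630) nor Abat (adjusted p = 0.0630) was called. Abat also missed the threshold with sex left out (adjusted p = 0.543) with the title letter as a covariate in the absence of replicate 2 (adjusted p = 0.0678) and without ambulatory control replicate 1 (adjusted p = 0.0507), a library left out after the data were seen.

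**Figure D1:**
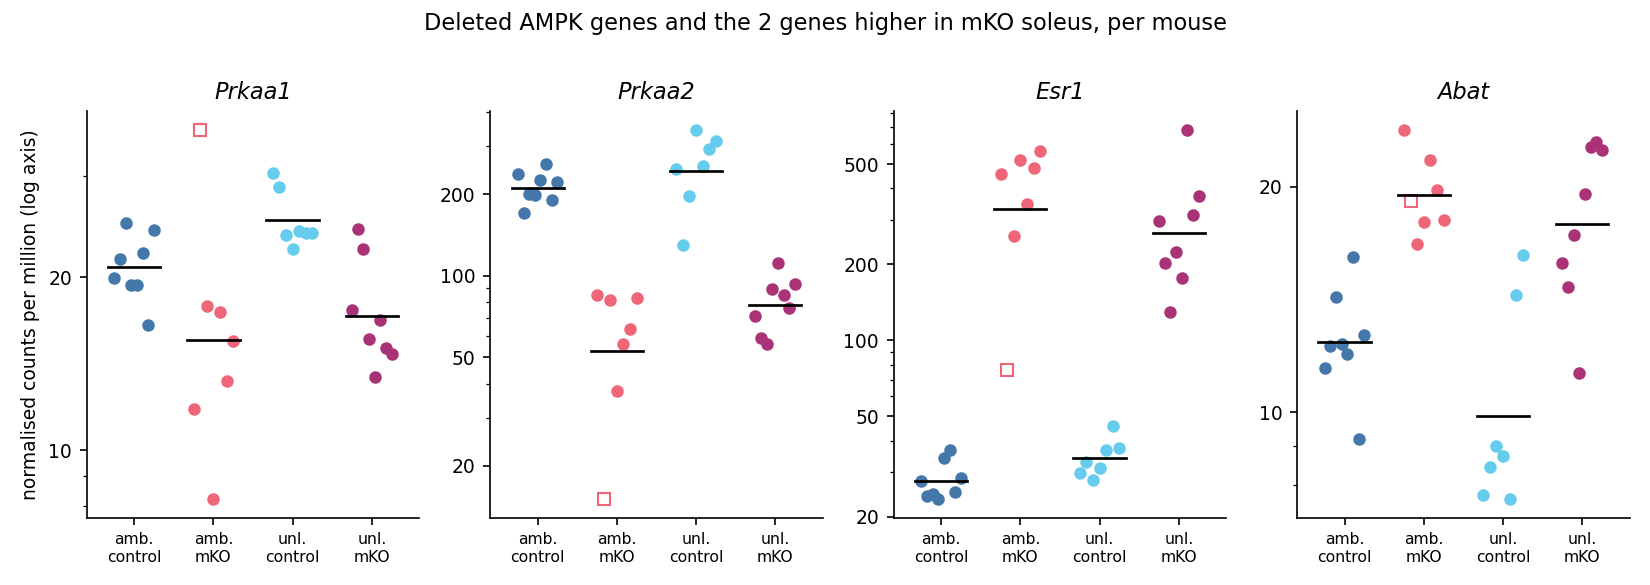
Normalised CPM (log axis) of Prkaa1, Prkaa2, Esr1 and Abat in each mouse of the 4 groups (amb., ambulatory; unl., unloaded). Points are mice, black lines are geometric means, and the open square is ambulatory mKO replicate 2; the lowest Esr1 value among the 15 mKO mice, 76.6 CPM, lies above the highest of the 15 controls, 46.0 CPM.

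Gene groups separated the genotypes less clearly than these single genes in ambulatory mice. Among 14 tested immediate early genes, which respond within minutes to activity and growth signals, 12 had lower values in mKO mice, with none called over all genes and 2 lower adjusted over the list alone. Egr1 measured log2 -1.29 ± 0.39 SE, Fos -1.12 ± 0.44 and Btg2 -0.66 ± 0.18. Their median was -0.44 with a camera adjusted p = 2.74e-06, and adjusted p = 0.114 with an estimated correlation. Egr1 was high in ambulatory control replicates 2, 4 and 5 (26.7 to 42.9 CPM), and the other controls lay within the mKO range. All 12 endothelial markers had lower values, Vwf at -0.45 ± 0.19, Kdr at -0.35 ± 0.17 and Pecam1 at -0.23 ± 0.11, with none called over all genes or adjusted over the list alone. The endothelial list had a median of -0.27 and a camera adjusted p = 3.29e-05, and adjusted p = 0.209 with an estimated correlation. Markers of pericytes and smooth muscle had a median of -0.23 over 9 genes, with none called over all genes and 1 lower adjusted over the list alone, Cnn1 at -1.68 ± 0.39. This pericyte list had a camera adjusted p = 0.000896, and adjusted p = 0.36 with an estimated correlation.

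All 47 nuclear-encoded subunits and carriers of oxidative phosphorylation had lower values in ambulatory mKO mice, but none passed over all genes or adjusted over the list alone. Cox6c measured log2 -0.59 ± 0.24 SE. Their median of -0.29 (camera adjusted p = 1.43e-20, and adjusted p = 0.36 with an estimated correlation) moved with ambulatory mKO replicate 2 and was -0.11 without that library. The 13 mitochondrially encoded transcripts had a median of -0.42, which was -0.19 without it, with no call over all genes or adjusted over the list alone. Ambulatory mKO replicate 4, kept in both medians, had 1.01% of its counts in mitochondrial genes, the lowest share of the 30 libraries. How far the remaining difference rests on replicate 4 is not given here. The mitochondrially encoded list had a camera adjusted p = 3.21e-06, and adjusted p = 0.482 with an estimated correlation. The 12 slow fibre genes had a median of -0.33 and no call over all genes or adjusted over the list alone. This slow fibre list had a camera adjusted p = 5.12e-08, and adjusted p = 0.36 with an estimated correlation. Without replicate 2 their median was -0.03 and the camera call ended (adjusted p = 0.268). Adipocyte markers had a median of 2.17 over 10 genes, Adipoq at 2.40 ± 1.05 and Cfd at 2.22 ± 0.93, with no call over all genes or adjusted over the list alone (camera adjusted p = 0.00419, and adjusted p = 0.565 with an estimated correlation), and a median of 0.51 without that library (camera adjusted p = 0.92). The 14 fast fibre genes went the other way, from a median of 0.03 (camera adjusted p = 0.974) to 0.28 without it (adjusted p = 2.99e-05). None was called over all genes or adjusted over the list alone, and without that library adjusted p = 0.633 with an estimated correlation. Myh4 in that list varied widely within both genotypes. It ran from 19.7 to 2861 CPM in ambulatory mKO mice. Control replicates 1 and 8 held 4658 and 1147 CPM, and the other controls 13.8 to 28.6 CPM. Whether the list value reflects genotype or such spread between mice was not tested. In all, camera with a preset correlation called 20 of 35 lists, 4 higher and 16 lower in mKO mice, and 10 without replicate 2, of which 5 were among the 20. With an estimated correlation it called 0 of 35, the 20 lists having adjusted p between 0.114 and 0.641.

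In unloaded mice the same 3 genes separated mKO from control and none besides them was called. Esr1 rose 8.58-fold, from 34.6 ± 6.12 CPM (SD, n = 7) in controls to 300.3 ± 175 CPM (SD, n = 8) in mKO mice (log2 3.10 ± 0.33 SE, adjusted p = 5.16e-06). Prkaa2 fell 3.11-fold, from 254 ± 73.2 to 80.1 ± 18.5 CPM (log2 -1.64 ± 0.24 SE, adjusted p = 0.00192), with every mKO mouse below every control. Abat rose 1.71-fold, from 10.3 ± 3.47 to 18.3 ± 4.26 CPM (log2 0.77 ± 0.14 SE, adjusted p = 0.0268), with overlapping ranges and the same direction in all 3 title letters. Prkaa1 measured 25.3 ± 2.98 CPM in controls and 17.5 ± 3.88 CPM in mKO mice and was not called (log2 -0.60 ± 0.18 SE, unadjusted p = 0.00239).

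At an unadjusted p below 0.05 there were 301 genes between unloaded mKO and control mice, against about 847 by chance. That count was 469 without ambulatory mKO replicate 2 and 398 with the title letter as a covariate. A count below the chance level does not show that no further gene differs. DESeq2 called 3. The Abat call ended without a low-count filter (adjusted p = 0.0800), with sex left out (adjusted p = 0.128) and in a model of the compared groups alone (adjusted p = 0.621).

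In unloaded mice camera called 8 lists between mKO and control with a preset correlation, and none with an estimated one. No gene of these 8 lists was called over all genes. All 14 fast fibre genes had higher values (median log2 0.38, among them Pvalb at 0.48 ± 0.40 SE and Mylpf at 0.38 ± 0.31), with none adjusted over the list alone. The camera adjusted p was 0.0118, and adjusted p = 0.917 with an estimated correlation. All 14 macrophage markers had lower values (median -0.34, C1qc at -0.51 ± 0.25 and Adgre1 at -0.53 ± 0.28), with none adjusted over the list alone. The macrophage list had a camera adjusted p = 0.00059, and adjusted p = 0.917 with an estimated correlation. Tenocyte markers had a median of -1.09 over 8 genes, with the matrix proteins Chad at -1.88 ± 0.92 and Comp at -1.68 ± 0.83, and none adjusted over the list alone. This tenocyte list had a camera adjusted p = 0.0411, and adjusted p = 0.917 with an estimated correlation. Markers of fibro-adipogenic progenitors had a median of -0.35, with Pi16 at -0.91 ± 0.42 and none adjusted over the list alone. The progenitor list had a camera adjusted p = 0.0066, and adjusted p = 0.917 with an estimated correlation. The adipocyte markers had a median of 0.95 with Fabp4 at 0.85 ± 0.52. That adipocyte list had a camera adjusted p = 0.0411, and adjusted p = 0.917 with an estimated correlation. The difference rested on unloaded mKO replicates 2 and 3, at 200.4 and 199.0 CPM of Adipoq against 3.00 to 41.3 CPM in the other 6 mice of the group. Without these libraries and ambulatory mKO replicate 2, Fabp4 measured 0.15 and the list had a median of -0.066 (camera adjusted p = 0.893). Genes of lipid and sterol synthesis had a median of 0.16 (camera adjusted p = 0.046, and adjusted p = 0.917 with an estimated correlation). Nuclear-encoded oxidative phosphorylation had one of -0.08 (camera adjusted p = 0.0312, and adjusted p = 0.917 with an estimated correlation). The integrated stress and unfolded protein responses had one of -0.11 (camera adjusted p = 0.046, and adjusted p = 0.341 with an estimated correlation). None of the genes of these 4 lists passed adjusted over the list alone. Without the 3 adipocyte-rich libraries the lipid list had a median of -0.14 (camera adjusted p = 0.799) and oxidative phosphorylation one of -0.012 with 21 of 47 genes higher (camera adjusted p = 0.992), so both calls ended. The mean of the stress list was near 0 (-0.0022), and Hspa5 in it measured -0.39 ± 0.17. Camera thus called 8 lists in all, 3 higher and 5 lower, and 0 of 35 with an estimated correlation; it called 13 without ambulatory mKO replicate 2. Without the 3 adipocyte-rich libraries it called 16, 9 higher and 7 lower, of which 5 were among the 8, and 0 with an estimated correlation. Schwann cell markers then turned from a median of 0.28 to -1.44 (camera adjusted p = 0.00984, and adjusted p = 0.821 with an estimated correlation), and collagens and matrix had one of -0.40 (camera adjusted p = 0.0166, and adjusted p = 0.985 with an estimated correlation).

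Unloading changed far more of the soleus transcriptome than genotype did. In control mice, edgeR called 1882 of 16932 genes after 4 weeks of unloading, 910 higher and 972 lower. Of these, 290 rose and 306 fell at least 2-fold. Some fast fibre transcripts rose, and many genes of fat oxidation, the respiratory chain, matrix, heat shock and load sensing fell. The ketone body enzyme Bdh1 fell 8.23-fold (log2 -3.04 ± 0.40 SE, adjusted p = 3.69e-05), the matrix protein Postn fell 7.78-fold (-2.96 ± 0.58, adjusted p = 0.00149) and the cytokine receptor Tnfrsf12a fell 7.16-fold (-2.84 ± 0.47, adjusted p = 0.000346). Col1a1 (-2.74 ± 0.84), embryonic myosin Myh3 (-2.74 ± 0.50), Slc6a18 (-3.03 ± 0.78), Adamts8 (-2.72 ± 0.72) and Lrrc52 (-2.67 ± 0.60) were the other largest falls among genes with an official symbol and a mean of at least 1 CPM. The synaptic vesicle gene Sv2b rose 7.15-fold (2.84 ± 0.45, adjusted p = 0.000271), the GABA receptor subunit Gabrr2 rose 5.66-fold (2.50 ± 0.36, adjusted p = 8.77e-05) and the signalling ligand Wnt4 rose 5.64-fold (2.49 ± 0.45, adjusted p = 0.000713). Ccdc192 (2.77 ± 0.44), Mybph (2.46 ± 0.73), Dmkn (2.44 ± 0.55), the fast fibre α-actinin Actn3 (2.28 ± 0.53) and Myhas (3.10 ± 0.55), an antisense RNA of the fast myosin cluster, were the other largest rises. The strand setting of the counting was not given in the sources used here, so it is not known whether the counts of Myhas hold reads of the myosins it overlaps.

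Myosins 2X and 2A and a few other fibre-type genes changed in unloaded controls. Myosin 2X, Myh1, rose 3.68-fold, from 4654 ± 2477 CPM (SD, n = 8) to 17493 ± 8978 CPM (SD, n = 7), with log2 1.88 ± 0.53 SE and adjusted p = 0.0214. Myosin 2A, Myh2, fell 6.24-fold, from 11643 ± 4506 to 2195 ± 1989 CPM (log2 -2.64 ± 0.60 SE, adjusted p = 0.00486). Myh2 stood outside the rule for named genes in this comparison and was chosen after its values were seen. Myosin 2B, Myh4, went from 741 ± 1631 to 5352 ± 2296 CPM without passing (log2 3.06 ± 1.06 SE, adjusted p = 0.0588), though DESeq2 (adjusted p = 0.0142) and the title letter as a covariate (adjusted p = 0.0215) called it. Ambulatory control replicate 1 held 4658 CPM of Myh4 and replicate 8 held 1147 CPM, against 13.8 to 28.6 CPM in the other 6, and with replicate 1 left out Myh4 rose (log2 4.88, adjusted p = 0.0063). The slow myosin Myh7 did not pass (log2 -0.60 ± 0.49 SE). Of 14 fast fibre genes 8 had higher and 6 lower values, and 3 rose and none fell (5 rose adjusted over the list alone), with Pvalb, a calcium buffer of fast fibres, at 1.54 ± 0.39. Camera gave the list an adjusted p = 0.0318, and adjusted p = 0.761 with an estimated correlation. All 12 slow fibre genes had lower values and none passed over all genes or adjusted over the list alone, with Pln at -1.15 ± 0.39, Myl3 at -1.12 ± 0.42 and Casq2 at -0.92 ± 0.35. The slow fibre list had a camera adjusted p = 0.0115, and adjusted p = 0.735 with an estimated correlation. Without ambulatory mKO replicate 2, which enters this comparison through the estimate of spread, 6 of the 12 fell, among them Pln (adjusted p = 0.0313), Myl3 (adjusted p = 0.00118) and Casq2 (adjusted p = 0.000675). Adult myosin genes are alike in sequence, and how reads shared between them were counted is not stated.

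**Figure D2:**
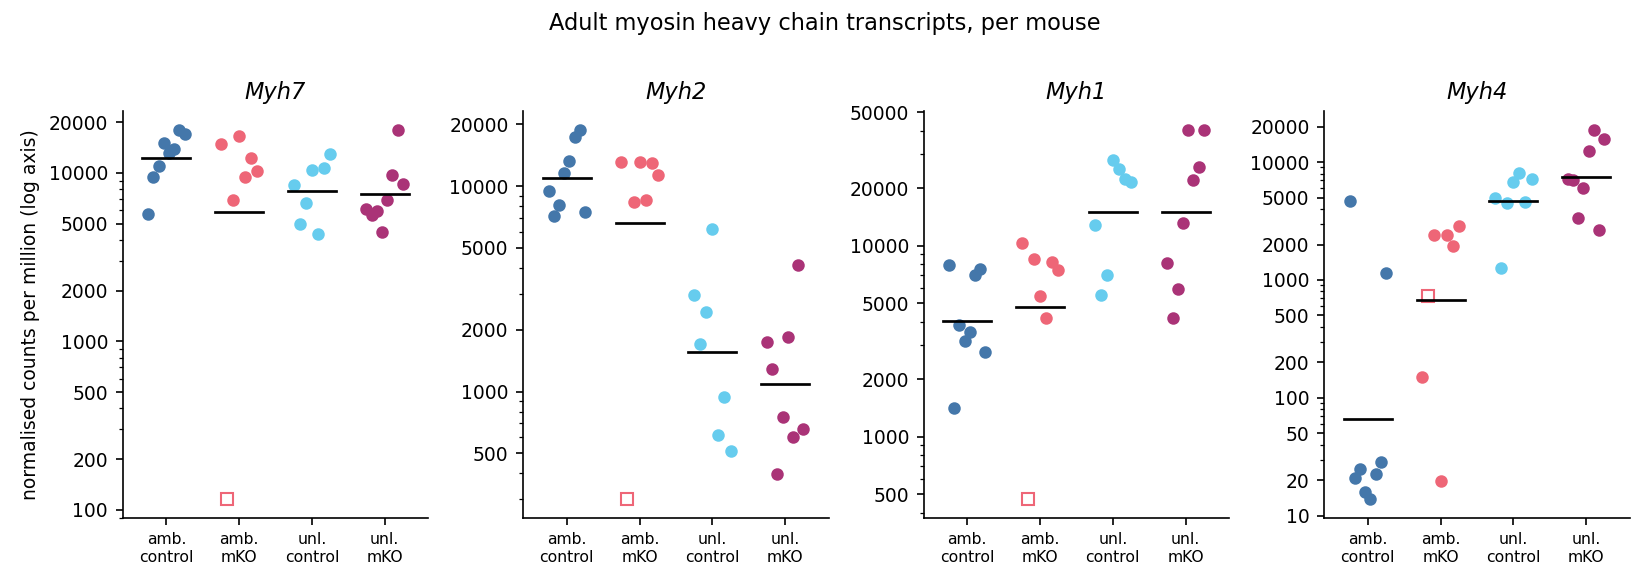
Normalised CPM (log axis) of the adult myosin heavy chains Myh7 (slow), Myh2, Myh1 and Myh4 (fast) in each mouse of the 4 groups (amb., ambulatory; unl., unloaded). Points are mice, black lines are geometric means and the open square is ambulatory mKO replicate 2; in controls the mean of Myh2 went from 11643 CPM in ambulatory to 2195 CPM in unloaded mice.

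Some genes of oxidative metabolism fell in unloaded controls and few rose. Of 47 nuclear-encoded genes of oxidative phosphorylation 15 fell and none rose (28 fell adjusted over the list alone, and 30 fell over all genes without ambulatory mKO replicate 2), with Ndufs8 at log2 -0.86 ± 0.19 SE, Uqcrq at -0.85 ± 0.19 and cytochrome c, Cycs, at -0.90 ± 0.21. The camera adjusted p was 5.58e-13, and adjusted p = 0.517 with an estimated correlation. Of 24 genes of fatty acid uptake and oxidation 11 fell and none rose (14 fell adjusted over the list alone), with the fatty acid carrier Fabp3 falling 4.44-fold (-2.15 ± 0.49), Acaa2 at -0.99 ± 0.22, Eci1 at -0.90 ± 0.20 and Hadh at -0.81 ± 0.18. The fat oxidation list had a camera adjusted p = 5.01e-08, and adjusted p = 0.457 with an estimated correlation. Of 17 genes of the tricarboxylic acid cycle 4 fell and none rose (7 fell adjusted over the list alone, and 8 over all genes without ambulatory mKO replicate 2), with Idh2 at -1.25 ± 0.33 and Mdh1 at -0.93 ± 0.21. The cycle as a list had a camera adjusted p = 4.5e-06, and adjusted p = 0.586 with an estimated correlation. Their regulators Ppargc1a (-1.62 ± 0.46), Esrrg (-1.30 ± 0.39) and Ppara (-1.28 ± 0.30) fell as well. They belong to a list on mitochondrial biogenesis of which 4 of 24 fell and 1 rose, also when adjusted over the list alone, and which camera did not call (adjusted p = 0.17). Glycolysis and glycogen genes went both ways, with 2 of 23 rising, Gpd1 at 1.41 ± 0.34 and Phkg1 at 1.22 ± 0.25, and 2 falling, among them Hk2 at -0.84 ± 0.28, the same counts adjusted over the list alone (camera adjusted p = 0.744). Prkag3, the AMPK γ3 subunit of fast fibres, rose 3.19-fold (1.67 ± 0.29) and was the only of 7 AMPK subunits to rise, also adjusted over the list alone (camera adjusted p = 0.313), while Prkaa1 (0.34 ± 0.18) and Prkaa2 (0.22 ± 0.24) did not pass.

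Some load-sensing, heat shock and matrix genes fell in unloaded controls. Of 10 load-sensing sarcomere genes 5 fell and none rose (7 fell adjusted over the list alone), led by Ankrd1 at log2 -2.56 ± 0.60 SE, Ankrd2 at -1.91 ± 0.42 and Xirp1 at -1.80 ± 0.38. The load-sensing list had a camera adjusted p = 2.36e-05, and adjusted p = 0.457 with an estimated correlation. Of 16 heat shock genes 10 fell and none rose (11 fell adjusted over the list alone), with Hspa1b at -2.22 ± 0.38, Hspa1a at -2.20 ± 0.41 and the lens and muscle chaperone Cryab at -1.63 ± 0.33. Hspa1a and Hspa1b are near-identical copies whose counts are not independent. This list's camera adjusted p was 1.5e-07, and adjusted p = 0.23 with an estimated correlation, or adjusted p = 0.011 with an estimated correlation when ambulatory mKO replicate 2 was left out. Of 32 collagen and matrix genes 10 fell and none rose (14 fell adjusted over the list alone), with Timp1 at -2.47 ± 0.71, Col15a1 at -1.35 ± 0.32 and Col4a1 at -1.10 ± 0.33. Camera gave the matrix list an adjusted p = 1.05e-06, and adjusted p = 0.586 with an estimated correlation. The Col1a1 call (adjusted p = 0.0335) ended with the title letter as a covariate (adjusted p = 0.0670). Immediate early genes fell in 6 of 14 cases and rose in none (7 fell adjusted over the list alone), with Atf3 at -1.93 ± 0.43, Btg2 at -1.04 ± 0.17 and Jun at -0.74 ± 0.19. The immediate early list had a camera adjusted p = 3.69e-05, and adjusted p = 0.23 with an estimated correlation. Among cell-type markers, 4 of 12 endothelial genes fell (7 adjusted over the list alone), with Kdr at -1.07 ± 0.17 and Eng at -0.81 ± 0.15. This endothelial list had a camera adjusted p = 0.000113, and adjusted p = 0.23 with an estimated correlation. The angiogenic factor Vegfa fell 3.24-fold. Pericyte and smooth muscle markers fell in 4 of 9 cases (5 adjusted over the list alone), with Cnn1 at -1.75 ± 0.38. Camera gave them an adjusted p = 0.00281, and adjusted p = 0.454 with an estimated correlation. Of 8 tenocyte markers 1 fell, Scx at -1.81 ± 0.46, also adjusted over the list alone. The tenocyte list had a camera adjusted p = 0.0495, and adjusted p = 0.735 with an estimated correlation.

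Few genes of protein breakdown passed in unloaded controls after 4 weeks. In the atrophy list 1 of 20 genes rose, the ubiquitin ligase Cblb (log2 0.58 ± 0.18 SE), with none adjusted over the list alone and a camera adjusted p = 0.0963. The ligase Trim63 measured -0.67 ± 0.35 (adjusted p = 0.227). No proteasome subunit among 31 passed over all genes or adjusted over the list alone, and their median was -0.14. The proteasome list had a camera adjusted p = 0.0299, and adjusted p = 0.901 with an estimated correlation. In the autophagy and lysosome list 3 of 24 fell, with Gabarapl1 at -1.24 ± 0.17 and Ctsd at -0.63 ± 0.12, and Ctsl rose by 0.68 ± 0.16 (4 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.135). Redox genes split, with 4 of 19 rising, led by the cystine transporter Slc7a11 at 2.77 ± 0.50, Hmox1 at 1.39 ± 0.29 and Gclm at 0.87 ± 0.16, and 2 falling, the same counts adjusted over the list alone (median -0.08, mean 0.19, camera adjusted p = 0.964). Denervation and junction genes also split, with Hdac4 (1.07 ± 0.20) and Gadd45a (0.99 ± 0.28) among 3 of 20 that rose and Colq (-1.56 ± 0.42) among 2 that fell, again the same adjusted over the list alone (camera adjusted p = 0.744). The stress-response list had Chac1 (2.03 ± 0.45) among 2 of 16 that rose and Mthfd2 (-0.82 ± 0.23) among 2 that fell, with 2 rising and 3 falling adjusted over the list alone (camera adjusted p = 0.744). In the senescence and secretory list Vegfa was among 2 of 17 that fell and Igfbp5 (1.01 ± 0.28) rose, with 3 falling and 2 rising adjusted over the list alone (camera adjusted p = 0.313). Ribosomal protein genes had 23 of 27 higher values, of which 2 rose, Rpl30 (0.57 ± 0.14) and Rpl5 (0.48 ± 0.13), also adjusted over the list alone. The ribosomal protein list had a camera adjusted p = 0.000538, and adjusted p = 0.64 with an estimated correlation. Clock genes rose in 3 of 16 cases (5 adjusted over the list alone), Per3 at 0.74 ± 0.23, Hlf at 0.71 ± 0.22 and Tef at 0.51 ± 0.16. The clock list had a camera adjusted p = 0.00198, and adjusted p = 0.327 with an estimated correlation. The lipogenic regulator Mlxipl fell by 0.98 ± 0.13 and the polyamine enzyme Odc1 by 0.70 ± 0.13, the only called genes of their lists. These counts moved with ambulatory mKO replicate 2, which enters through the estimate of spread. Without it 3 atrophy genes rose and 1 fell, 3 proteasome subunits fell and camera did not call that list (adjusted p = 0.0530). Also without it 5 ribosomal protein and 5 clock genes rose, 4 junction genes rose and 3 fell, and 2 genes of the senescence list rose and 3 fell.

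These calls come from edgeR with 7 unloaded and 8 ambulatory controls. Camera called 15 of 35 lists with a preset correlation, 12 lower and 3 higher, and 0 with an estimated correlation. The number of called genes was 1225 without a low-count filter, 3098 in a model of the control groups alone and 4257 with library weights, and Mybph lost its call in each of these.

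Unloading also changed soleus transcripts of mKO mice, with 1702 genes called, 897 higher and 805 lower. Of these, 316 rose and 226 fell at least 2-fold. Fibrillar collagens were among the largest falls: Col1a1 fell 15.1-fold (log2 -3.92 ± 0.91 SE, adjusted p = 0.00765), Col1a2 fell 8.08-fold (-3.01 ± 0.76, adjusted p = 0.0121) and Col3a1 fell 6.12-fold (-2.61 ± 0.54, adjusted p = 0.00379). Ambulatory mKO replicate 4 held 13334 CPM of Col1a1, against 192 to 4853 CPM in the other 6 mice of its group. Without it Col1a1 fell 7.26-fold (-2.86, adjusted p = 0.0249), Col1a2 4.44-fold (-2.15, adjusted p = 0.0453) and Col3a1 4.32-fold (-2.11, adjusted p = 0.0105). The nicotinamide riboside kinase Nmrk2 (-2.78 ± 0.66), Timp1 (-2.57 ± 0.76), Tecta (-2.52 ± 0.49), Myh2 (-2.48 ± 0.59) and Adrb3 (-2.92 ± 0.79), a β-adrenergic receptor of adipocytes, were the other largest falls. Adrb3 was not called without ambulatory mKO replicate 2, the library rich in adipocyte transcripts (log2 -1.59, adjusted p = 0.221). Ccdc192 rose 11.1-fold (3.48 ± 0.48, adjusted p = 0.000132), Nek10 9.26-fold (3.21 ± 0.65, adjusted p = 0.00318) and Sv2b 7.51-fold (2.91 ± 0.49, adjusted p = 0.000713). Odf3l2 (3.11 ± 0.97), Slc22a12 (2.69 ± 0.57), Myhas (2.64 ± 0.58), Gabrr2 (2.60 ± 0.38) and Chrne (3.14 ± 1.00), the adult subunit of the acetylcholine receptor, were the other largest rises. Chrne lost its call without replicate 2 (adjusted p = 0.0731) and without replicate 4 (adjusted p = 0.0739), and Odf3l2 without replicate 4 (adjusted p = 0.0718).

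Some fast fibre genes also rose in mKO mice. Myh1 rose 3.45-fold (log2 1.78 ± 0.56 SE), Actn3 4.22-fold (2.08 ± 0.57) and Pvalb 2.49-fold (1.31 ± 0.42), and these were 3 of 14 fast fibre genes that rose while none fell (5 rose adjusted over the list alone). The camera adjusted p was 0.000529, and adjusted p = 0.685 with an estimated correlation. Without ambulatory mKO replicate 2, Pvalb (adjusted p = 0.0731) and the list (camera adjusted p = 0.119) were no longer called. Myh2 fell 5.58-fold, whereas Myh4 (3.40 ± 1.19, adjusted p = 0.0644) and Myh7 (-0.41 ± 0.52) did not pass; DESeq2 called Myh4 (adjusted p = 0.00751). None of 12 slow fibre genes passed over all genes or adjusted over the list alone, and their median of -0.43 went against the upward direction of camera (adjusted p = 0.692). Without replicate 2, which held little fibre RNA, 6 of the 12 fell, among them Myl3 (-1.33, adjusted p = 0.000524) and Casq2 (-1.07, adjusted p = 0.000384), and camera called the list lower (adjusted p = 1.25e-05, and adjusted p = 0.343 with an estimated correlation).

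Fewer metabolic and load-sensing genes of mKO mice fell with ambulatory mKO replicate 2 in the model than without it. Of 24 genes of fatty acid uptake and oxidation 9 fell and none rose (13 fell adjusted over the list alone), with Fabp3 at log2 -2.22 ± 0.49 SE, Acaa2 at -1.02 ± 0.22 and Hadh at -0.81 ± 0.18. This fat oxidation list had a camera adjusted p = 4.43e-05, and adjusted p = 0.685 with an estimated correlation. Without that library 13 fell and the list was called as well (camera adjusted p = 3.13e-11, and adjusted p = 0.343 with an estimated correlation). Of 17 tricarboxylic acid cycle genes 5 fell and none rose, also adjusted over the list alone, with Idh2 at -1.12 ± 0.34 and Mdh1 at -0.88 ± 0.22. The cycle genes together had a camera adjusted p = 0.00311, and adjusted p = 0.687 with an estimated correlation. They were called without that library too (camera adjusted p = 1.02e-09, and adjusted p = 0.343 with an estimated correlation), and 9 fell. Of 47 nuclear-encoded oxidative phosphorylation genes only Cycs fell (-0.73 ± 0.22) and none adjusted over the list alone. Camera gave them an adjusted p = 0.00483, and adjusted p = 0.797 with an estimated correlation. Without ambulatory mKO replicate 2, 21 of the 47 fell. Of 10 load-sensing genes 3 fell, Ankrd1 (-2.07 ± 0.61), Xirp1 (-1.42 ± 0.39) and Ankrd2 (-1.32 ± 0.43), with 4 adjusted over the list alone and no camera call (adjusted p = 0.0971). Without that library 7 fell and camera called the list (adjusted p = 6.46e-09, and adjusted p = 0.0875 with an estimated correlation). In the glycolysis list 1 of 23 rose, Phkg1 (1.39 ± 0.26), also adjusted over the list alone. Camera called that list higher (adjusted p = 0.00838, and adjusted p = 0.742 with an estimated correlation), but not without replicate 2 (adjusted p = 0.719). Prkag3 rose by 1.88 ± 0.31, again the only AMPK subunit of 7, also adjusted over the list alone (camera adjusted p = 0.213), and Prkaa1 (-0.06 ± 0.18) and Prkaa2 (0.48 ± 0.25) did not pass.

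Some matrix, chaperone and junction genes changed as well in unloaded mKO mice. Of 32 collagen and matrix genes 15 fell and none rose (22 fell adjusted over the list alone), with Col15a1 at log2 -1.51 ± 0.33 SE and Col6a3 at -1.48 ± 0.35 beside the fibrillar collagens. The matrix list had a camera adjusted p = 3.04e-08, and adjusted p = 0.685 with an estimated correlation, and 11 fell without ambulatory mKO replicate 2. Of 10 markers of fibro-adipogenic progenitors, the main matrix-producing cells of muscle, 2 fell (5 adjusted over the list alone), with a camera adjusted p = 0.00371, and adjusted p = 0.685 with an estimated correlation. Without ambulatory mKO replicate 2 none fell and camera did not call them (adjusted p = 0.14). Of 16 heat shock genes 6 fell and none rose (9 fell adjusted over the list alone), with Hspa1b at -1.68 ± 0.37, Hspa1a at -1.60 ± 0.40, Cryab at -1.31 ± 0.33 and Hspa8 at -0.78 ± 0.19. The camera adjusted p was 0.000678, and adjusted p = 0.685 with an estimated correlation, or adjusted p = 0.0115 with an estimated correlation without that library, when 10 fell. Of 20 denervation and junction genes 6 rose, among them Ache (1.68 ± 0.45), Hdac4 (1.45 ± 0.21) and Chrnb1 (1.04 ± 0.24), and 1 fell, Myh3 (-2.30 ± 0.53), with 7 and 1 adjusted over the list alone. Camera called this list higher (adjusted p = 0.0024, and adjusted p = 0.685 with an estimated correlation), though not without replicate 2 (adjusted p = 0.392), when 4 rose and 2 fell. Scx fell by 1.61 ± 0.48 and was the only tenocyte marker to fall, also adjusted over the list alone (camera adjusted p = 0.27, or without that library adjusted p = 0.0175, and adjusted p = 0.696 with an estimated correlation). Kdr fell by 0.85 ± 0.17, the only endothelial marker of 12 to do so (2 adjusted over the list alone, camera adjusted p = 0.122), and Vegfa fell 2.53-fold.

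Protein turnover genes of unloaded mKO mice showed few calls. None of the 20 atrophy genes passed over all genes or adjusted over the list alone, with Fbxo32 at log2 0.72 ± 0.37 SE, Foxo1 at 0.56 ± 0.29 and Cblb at 0.42 ± 0.18, and 18 of the 20 had higher values. The atrophy list had a camera adjusted p = 0.00953, and adjusted p = 0.685 with an estimated correlation. Without ambulatory mKO replicate 2, Foxo1 (0.95, adjusted p = 0.0235) and Cblb (0.62, adjusted p = 0.0168) rose. Autophagy and lysosome genes had 3 of 24 falling, with Gabarapl1 at -0.93 ± 0.16 and Ctsd at -0.52 ± 0.12, and Map1lc3a rising by 0.86 ± 0.21 (7 fell and 2 rose adjusted over the list alone, camera adjusted p = 0.195). Stress-response genes included Chac1 (1.78 ± 0.47), the only of 16 to rise, and Mthfd2 (-1.16 ± 0.24) and Hspa5 (-0.67 ± 0.18) among 3 that fell, with 1 and 4 adjusted over the list alone (camera adjusted p = 0.195). Redox genes again split, with Hmox1 (1.12 ± 0.28) and Gclm (0.76 ± 0.16) among 3 of 19 that rose and Srxn1 (-0.77 ± 0.17) among 4 that fell, with 3 and 5 adjusted over the list alone (camera adjusted p = 0.618). In the senescence and secretory list Vegfa and Igfbp7 (-1.14 ± 0.26) were among 4 of 17 that fell and Plaur (0.78 ± 0.21) rose, with 5 falling and 3 rising adjusted over the list alone (camera adjusted p = 0.103). Ribosomal protein genes rose in 4 of 27 cases, also adjusted over the list alone, with Rpl30 at 0.64 ± 0.15 and Rpl32 at 0.56 ± 0.13. Ribosomal protein genes together had a camera adjusted p = 0.00371, and adjusted p = 0.687 with an estimated correlation. No clock gene among 16 passed over all genes or adjusted over the list alone, although 14 had higher values. Clock genes together had a camera adjusted p = 0.00356, and adjusted p = 0.685 with an estimated correlation. In the interferon list 1 of 20 fell, also adjusted over the list alone. Camera called that list lower (adjusted p = 0.00871, and adjusted p = 0.687 with an estimated correlation), but not without replicate 2 (adjusted p = 0.392). Mlxipl fell by 0.62 ± 0.13 and Odc1 by 0.46 ± 0.14, each the only called gene of its list. Without replicate 2, 3 autophagy and 3 senescence genes rose and 3 of each fell, and 4 redox genes rose and 2 fell.

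The edgeR test compared 8 unloaded with 7 ambulatory mKO mice. Camera called 13 lists with a preset correlation, 6 higher and 7 lower, and 0 with an estimated correlation; without ambulatory mKO replicate 2 it called 13, of which 8 were the same lists. The number of called genes was 987 without a low-count filter, 608 in a model of the mKO groups alone and 2591 with the title letter as a covariate.

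**Figure D3:**
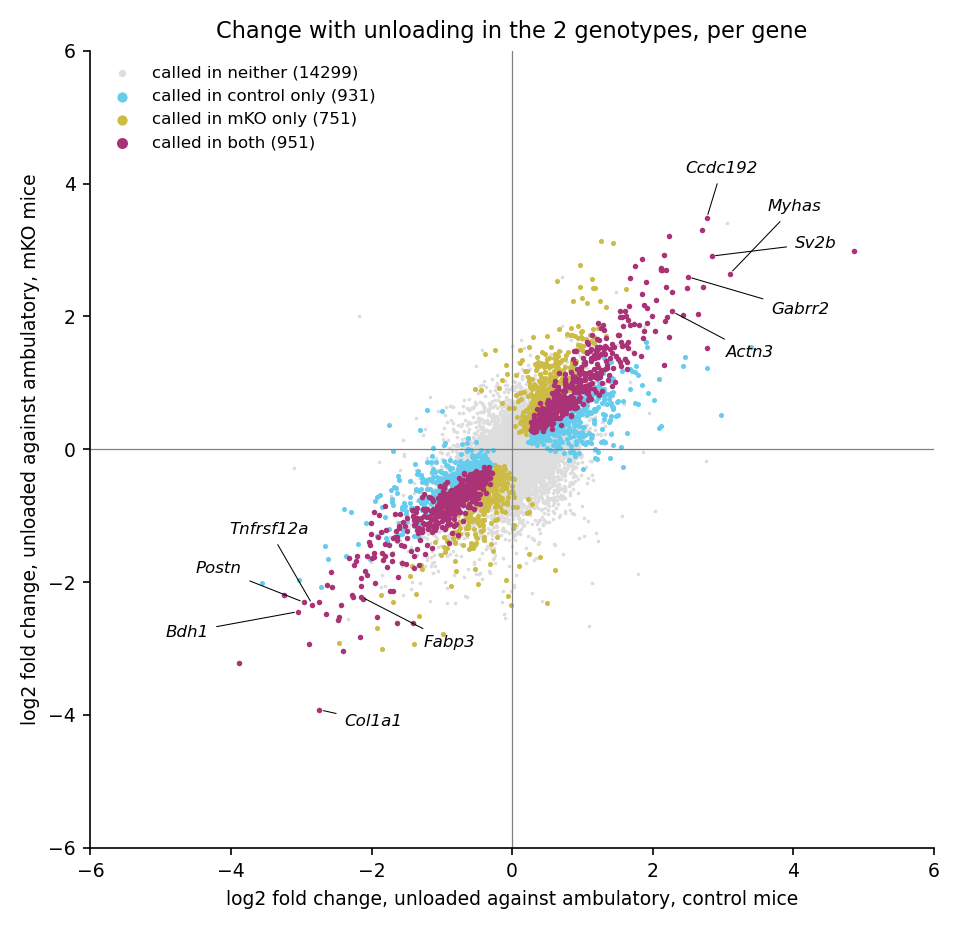
Each point is a gene, with its log2 fold change between unloaded and ambulatory mice in controls (horizontal axis) and in mKO mice (vertical axis). Colours give the genes called in both genotypes (951), in controls only (931), in mKO only (751) and in neither (14299); 1855 of the 1882 genes called in controls have the same sign in mKO mice.

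Whether unloading acts differently without muscle AMPK was tested by the overlap of both responses and by their interaction. Of the genes called for unloading, 1882 in controls and 1702 in mKO mice, 951 were called in both genotypes in the same direction. Among these, 486 rose in both, where independent lists would share 48.2, and 465 fell in both, against 46.2. Both sets of calls come from 1 fit with a shared estimate of spread, so independent lists are a low baseline. No gene was called in opposite directions, and 1855 of the 1882 genes called in controls (98.6%) had the same sign in mKO mice. Across all tested genes, which are not independent replicates, the log2 changes of both genotypes had a Pearson correlation of 0.68 and a Spearman correlation of 0.65, with no mouse in both. With ambulatory mKO replicate 2 left out, 738 genes rose and 843 fell in both genotypes.

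No gene passed the interaction test in edgeR, with 410 at an unadjusted p below 0.05 against about 847 by chance. The count was 218 without ambulatory mKO replicate 2 and 829 with the title letter as a covariate. A count that moves so with the model does not show that fewer genes differ than chance gives. DESeq2 called 0, with 459 at an unadjusted p below 0.05. The smallest p values belonged to the pro-apoptotic gene Bmf (log2 -0.81 ± 0.21 SE, unadjusted p = 0.000547), the smooth muscle gene Cnn1 (2.11 ± 0.57, unadjusted p = 0.000917) and Fam89a (1.80 ± 0.50, unadjusted p = 0.00116), and each had an adjusted p = 0.999. Genes called in controls alone (931) or in mKO mice alone (751) are therefore not shown to respond differently. On simulated data with the same groups, the interaction test found 29% of genes made to differ 2-fold and 85% of those made to differ 4-fold. The simulation held no outlying library and no effect of the letter, so these shares need not hold for the real data.

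Immediate early genes were the list that came closest to an interaction call with an estimated correlation. Their median log2 change with unloading was -0.68 in controls and -0.18 in mKO mice, and all 14 had a positive interaction, with Egr1 at 1.59 ± 0.53 SE and Fos at 1.52 ± 0.61, though none passed over all genes or adjusted over the list alone. The camera adjusted p was 2.19e-07, and adjusted p = 0.0502 with an estimated correlation. Leaving out ambulatory mKO replicate 2 gave a camera adjusted p = 9.39e-07, and adjusted p = 0.055 with an estimated correlation. Leaving out all 3 adipocyte-rich libraries, a setting chosen after the data were seen, gave adjusted p = 1.24e-07, and adjusted p = 0.0336 with an estimated correlation. For Egr1, ambulatory control replicates 2, 4 and 5 held 26.7, 42.9 and 27.9 CPM. The other ambulatory controls held 6.27 to 14.4 CPM, within the 5.11 to 14.8 CPM of ambulatory mKO mice. How far the whole list rests on those replicates was not tested. Pericyte and smooth muscle markers had a positive interaction in 8 of 9 cases, with none called over all genes and 3 higher adjusted over the list alone. The pericyte list had a camera adjusted p = 0.000157, and adjusted p = 0.388 with an estimated correlation. Macrophage markers all had a negative interaction, with none called over all genes or adjusted over the list alone (median -0.65, camera adjusted p = 9.34e-05, and adjusted p = 0.561 with an estimated correlation), and their median was -0.40 without replicate 2. Camera called 17 of 35 lists for the interaction with a preset correlation, 0 with an estimated correlation (adjusted p between 0.0502 and 0.601 for the 17). It called 6 without replicate 2, of which 5 were among the 17.

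**Figure D4:**
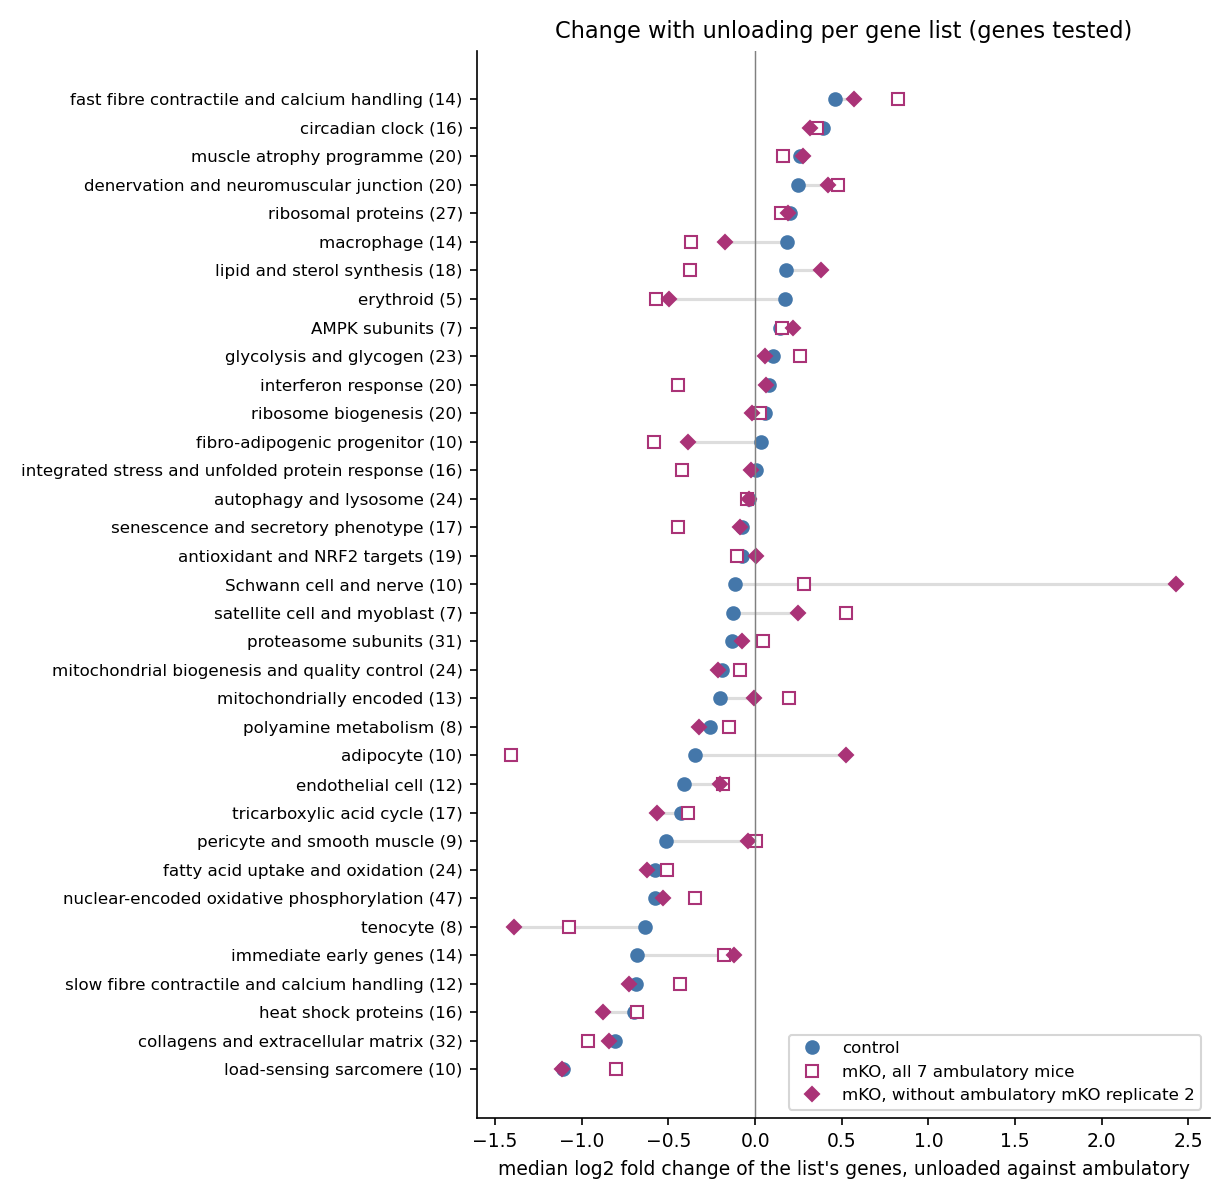
Median log2 fold change between unloaded and ambulatory mice (horizontal axis) of the tested genes of each list (vertical axis, number of genes in parentheses), in controls (circles), in mKO mice (open squares) and in mKO mice without ambulatory mKO replicate 2 (diamonds), with grey lines joining circles and diamonds. The load-sensing list lies at -1.11 in controls, -0.80 in mKO mice and -1.11 in mKO mice without that library, and the immediate early genes at -0.68, -0.18 and -0.12.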

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

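The tests of Esr1 against Acta1 and against other cell types, the 3 tests on ambulatory mKO replicate 2 and the test of Abat without that library were chosen only after the results were seen, as were the splits that keep the title letters and the demand that the relation of Esr1 to Acta1 also hold within title letters.

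The library of ambulatory mKO replicate 2 lay far from the other mice of its group. Its gap to the nearest mouse, as a share of the group's whole range, was 0.598 for the share of counts in the 10 highest genes, 0.886 for the slow fibre list, 0.762 for the fast fibre list, 0.751 for the satellite cell list and 0.753 for the Schwann cell list. For single genes it was 0.823 for Myh7, 0.882 for Myh2, 0.707 for Myh1, 0.613 for Esr1, 0.589 for Hspa1b, 0.815 for Fabp3 and 0.805 for Xirp1. Other mice far from their group were unloaded control 1 in the adipocyte list (0.757), ambulatory control 1 in the fast fibre list (0.548) and unloaded control 2 in Myh4 (0.679). In all, 15 of 108 tests, 27 measures in each of 4 groups, flagged a mouse, and most of these flags were ambulatory mKO replicate 2. Since chance gives about 1 in 20, about 5.4 flags would arise from independent measures. These measures are related, and the flags of the other mice are no more than chance could give.

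Low depth is argued against for ambulatory mKO replicate 2, since 3 libraries had lower totals and the lowest mean correlation of any of them with its group was 0.940, against 0.817 here. A wrong sex label is argued against by 1113 CPM of Xist and 0 of Ddx3y in a mouse labelled female. A candidate explanation is that the library held mostly tissue other than muscle fibres: 36 fibre genes had a median log2 difference of -4.04 from the other 6 mice, 35 of them lower, while 10 of 10 adipocyte markers (median 5.66) and 10 of 10 Schwann cell markers (median 5.19) were higher. Plin1 stood at 1094 CPM, and unloaded mKO replicates 2 and 3 also had high Adipoq (200.4 and 199.0 CPM). These 3 libraries were all the female mKO mice of title letter c. Female controls of letter c held 4.36 to 39.7 CPM of Adipoq, and the male ambulatory mKO replicate 3, also of letter c, held 142 CPM. High adipocyte transcripts thus coincided with 1 combination of genotype, sex and letter. Whether they came from dissection or from the muscle of these mice was not tested.

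Esr1 was higher in all 15 mKO than in all 15 control mice; a larger share of progenitor or endothelial cells is argued against, since 22 markers of them had a median log2 change of -0.089 (-0.33 to 0.62), a larger share of adipocytes, since Esr1 remained called without the 3 adipocyte-rich libraries (4.09 in ambulatory and 3.25 in unloaded mice), and a change of the whole region, since 6 neighbours had a median of -0.082 (-0.36 to 0.0048). Inducible Cre proteins carry part of an oestrogen receptor, so the reads may come from a Cre transgene driven by a skeletal actin promoter; the labels do not name the Cre line. Across the 15 mKO mice Esr1 followed Acta1 (Pearson 0.865, permutation p = 5.0e-05, and Spearman 0.796, permutation p = 0.00060). Adjusted over both genotypes these p were 1.0e-04 and 0.0012. Without the 2 mice farthest in Acta1 the correlations were 0.745 and 0.687. In 7 ambulatory mKO mice Pearson was 0.959 and Spearman 0.679 (0.770 and 0.486 without replicate 2). In 8 unloaded mKO mice Pearson was 0.740 and Spearman 0.738. Esr1 did not follow Acta1 in controls (Pearson -0.185, permutation p = 0.513, and Spearman -0.146, permutation p = 0.601). The permutation shuffled mice across conditions and letters, although letter c lay below letter b in both genes (Acta1 at most 16364 CPM, Esr1 at most 298 CPM). Its p values do not allow for that. With letter means removed Pearson was 0.740 and Spearman 0.679 over the 15 mice (0.578 and 0.508 without replicate 2). Within the 6 mice of letter b Pearson was -0.363 (Acta1 18586 to 26642 CPM), against 0.825 within the 4 of letter a. Within the 5 of letter c it was 0.899 (0.686 without replicate 2), and each letter held too few mice to settle the relation. A rise of Esr1 itself within fibres would also follow fibre RNA, so the relation cannot tell it from a transgene. The 2 cannot be told apart from gene counts.

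Abat was higher in mKO mice of both conditions. A change of its whole region is argued against, since 6 neighbours had a median log2 change of -0.0031 (-0.36 to 0.29), and so is an effect of the library poor in fibre RNA, since Abat remained called without it at 0.84 in ambulatory mice. A response of Abat to loss of AMPK stays open as a hypothesis and was not tested further, and the call depended on the model and, in ambulatory mice, on ambulatory control replicate 1 (0.81, adjusted p = 0.0507 without it).

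Camera called 17 lists for the interaction with a preset inter-gene correlation and none with an estimated one. The median log2 interaction was 0.19 for nuclear-encoded oxidative phosphorylation, 0.30 for mitochondrially encoded transcripts, 0.068 for mitochondrial biogenesis, 0.20 for glycolysis, 0.18 for slow fibre genes, 0.35 for load-sensing genes, 0.46 for denervation genes, 0.16 for proteasome subunits, 0.22 for heat shock proteins, 0.60 for immediate early genes, 0.34 for satellite cells, 0.21 for pericytes and smooth muscle, 0.26 for endothelium, -0.65 for macrophages, -0.60 for fibro-adipogenic progenitors, -0.41 for the interferon response and -0.78 for erythroid transcripts. Many of these values, though not all, rested on ambulatory mKO replicate 2. Without it 5 of the 17 lists were called, and the medians, in the order given, were -0.014, 0.081, -0.061, -0.033, -0.16, 0.020, 0.21, 0.034, 0.038, 0.43, 0.16, 0.22, 0.19, -0.40, -0.37, -0.083 and -0.70.

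Other splits of the same mice into groups of the same sizes, 40 with the real one, were tested for each comparison. With 40 splits no share below 1 in 40 can be seen, so chance can be argued against but not excluded. For unloading in controls it is argued against, with 1 split at the real 1882 genes and the highest other at 0. For unloading in mKO mice it is argued against as well, with 1 split at the real 1702 and the highest other at 848. What parts the mice in that split was not tested. For genotype in unloaded mice chance is argued against, with 1 split at the real 3 and the highest other at 0. For genotype in ambulatory mice it cannot be excluded from the count of genes, since 2 splits reached the real 3 and the highest other called 100, many times the real count, which points to a structure of the samples. What that structure is was not found, and the 11 other splits with letter b as uneven called at most 1 gene. Among 40 splits that kept the letters of each group, with the letter in the model, 1 reached the real 3 and the highest other called 0. These splits were chosen after the results were seen, so they do not overturn the planned result. In both genotype comparisons the 3 genes include Prkaa2, which was deleted by design. Such splits also left 1 at the real count for unloading in controls (2560, highest other 0) and in mKO mice (2591, highest other 949) and for genotype in unloaded mice (3, highest other 0). For the interaction the splits say nothing, since no split can call fewer than the real 0, which all 40 reached, and the highest other called 0.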

How the results depend on the processing

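Every setting that leaves out libraries was chosen only after the results were seen, and all others were planned. Of 136 calls of named genes, 136 held in DESeq2, 136 with median-of-ratios factors and 134 of 134 with a minimum of 1 CPM. With the title letter 133 held, 132 without sex, 131 with library weights, 111 without a low-count filter and 103 with only the compared groups. The count was 133 without ambulatory mKO replicate 2, 132 with the letter and without it, 135 without the 3 adipocyte-rich libraries, 127 without ambulatory mKO replicate 4 and 129 without ambulatory control replicate 1. By comparison, 1 of 3 calls held in every setting for genotype in ambulatory mice, 2 of 3 in unloaded mice, 60 of 72 for unloading in controls and 26 of 58 in mKO mice. Genes called for genotype in ambulatory mice (3) were 9 with DESeq2 and 1 with only the compared groups. For unloading in controls (1882) they were 1225 without a filter, where more genes share the adjustment, 4257 with library weights, 3098 with only the compared groups and 3355 with the letter and without replicate 2. For unloading in mKO mice (1702) they were 987 without a filter, 608 with only the compared groups and 2591 with the letter. Lists called for genotype in ambulatory mice (20) were 11 with library weights, 10 to 19 with 1 library left out (10 without replicate 2), 13 with the letter and without it, and 10 without the 3 libraries. In unloaded mice (8) they were 7 to 13 with 1 library left out (13 without replicate 2), 13 with the letter and without it, and 16 without the 3 libraries. For the interaction (17) they were 5 with library weights, 6 to 18 with 1 library left out (6 without replicate 2), 9 with the letter and without it, and 8 without the 3 libraries. With an estimated correlation 0 lists were called in all 5 comparisons, and without replicate 2 as well 0 in both genotype comparisons and the interaction and 1 in each of controls and mKO mice for unloading. Without the 3 libraries it called 0 in both genotype comparisons, 1 in each genotype for unloading (heat shock) and 1 for the interaction (immediate early genes). Prkaa1, not called, turned from -0.06 for unloading in mKO mice to 0.12 with library weights, 0.024 without sex, -0.18 to 0.27 with 1 library left out (0.27 without replicate 2), 0.17 with the letter and without it, and 0.12 without the 3 libraries. Prkaa2, not called, turned from 0.26 for the interaction to -0.045 with library weights. Beyond the filter the cause was not tested. No paired analysis was possible because the labels give no replicate numbers that join mice of different groups. In simulated counts with the real library sizes the procedure found 55% to 63% of 2-fold changes between 2 groups and 29% in the interaction. Most simulated 2-fold differences in the interaction were thus missed. The simulated genes were drawn independently, with no outlying library and no effect of the letter, and only genes with a mean of at least 1 CPM were changed. The shares found in the real data may therefore differ and are not known.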

Other observations

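The comparison of title letters was chosen only after the results were seen, and the test of sex and unloading was planned.

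Sex was called in 36 soleus genes, those of the sex chromosomes included, 9 higher in females and 27 higher in males over all 30 mice. At an unadjusted p below 0.05 there were 2139 genes (12.6%) against about 847 by chance, so further differences by sex may have stayed below the threshold; the examples were chosen after their values were seen. The peptide transporter gene Slc15a5 (log2 female minus male -3.26, adjusted p = 6.57e-08), the zinc transporter Slc30a2 (-2.22, adjusted p = 5.85e-07), the complement component C7 (-2.68, adjusted p = 6.69e-06) and Prune2 (-1.39, adjusted p = 0.00101) were higher in males. The aldo-keto reductases Akr1cl (5.73, adjusted p = 0.000717) and Akr1c14 (1.05, adjusted p = 0.00245), enzymes of steroid metabolism, were higher in females, Akr1cl with a mean of 4.32 CPM in females and 0.0878 CPM in males. Whether the response to unloading differed by sex was tested as a hypothesis. In edgeR 0 genes passed the interaction of sex and unloading. Those at an unadjusted p below 0.05 numbered 798 (4.71%) against about 847 by chance, which does not show that the sexes responded alike. Neither test of sex had the title letter in the model. Letter a held mostly males and letter b mostly females, and among unloaded mice a held only males and b only females. Sex and letter are therefore not fully separated in either test.

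Mice whose title ends in c had other soleus transcripts than those ending in a or b. With group and sex in the model and without the 3 libraries highest in adipocyte transcripts, 3669 genes differed between c and the mean of a and b, 1656 higher and 2013 lower, whereas b and a differed in 0 genes, with 1515 at an unadjusted p below 0.05; DESeq2 was not run on this comparison. Single genes chosen after their values were seen, which stand for no group of genes, include Ryr1 (log2 -0.90, adjusted p = 0.00277), Cacna1s (-0.94, adjusted p = 0.000938), Plec (-0.97), Jup (-1.10), Mafa (-1.52), Foxo6 (-1.49) and Flrt1 (-3.27), lower in c, and Angptl4 (1.27), Ppargc1a (0.97), Fabp3 (0.79) and Pi16 (1.08), higher in c. Of 23 glycolysis genes 7 were lower (camera adjusted p = 0.00988) and of 16 clock genes 4 were lower (camera adjusted p = 0.0283). Of 14 fast fibre genes 2 were lower (camera adjusted p = 0.0273). Of 31 proteasome subunits 5 were lower and 1 higher, and of 20 denervation and junction genes 5 were lower (camera adjusted p = 0.0283 for both lists). Of 27 ribosomal protein genes 8 were higher, and of 10 fibro-adipogenic progenitor markers 4 were higher (camera adjusted p = 0.0241 for both lists). Each of these lists had a camera adjusted p = 0.967 with an estimated correlation. The letter may mark cohorts of mice or days of work, which the 3669 genes would allow, but its meaning is not labelled. Every group held all 3 letters, so the letter is not fully confounded with genotype or unloading. The 3 libraries left out here were all mKO mice of letter c. In this fit letter c therefore held fewer mKO than control mice, and its mKO mice were all male. The letter is also partly tied to sex, mostly male in a and mostly female in b. The 0 genes between b and a therefore do not show that these letters are alike.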
